A study of Mus musculus domesticus and Mus musculus molossinus with 8 samples.

How the data were processed

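Polyadenylated RNA was sequenced from the liver and the thymus of 4 mice, 1 C57BL/6 (B6) and 1 MSM/Ms (MSM) per treatment, which gave 8 libraries in 8 groups of 1 library each. According to the submitters' processing notes, reads were aligned to mm10 with TopHat and gene levels were computed with Cuffdiff 2.2.1. The authors deposited gene FPKM (fragment counts scaled by transcript length and by mapped fragments) in 1 table for the untreated mice and 1 table for the injected mice, each normalized separately. The gene annotation and the run settings were not given in the sources used here. Both tables held 23284 genes, every value carried the status OK, and the step that leaves out other statuses removed none. MSM reads were aligned to mm10, a reference built from C57BL/6, so MSM genes whose sequence is divergent can lose reads. Gene symbols were kept as deposited, some of them older names (Gm129 for Ciart, Ccrn4l for Noct, Emr1 for Adgre1, Sc4mol for Msmo1). Of these genes, 20887 had a GENCODE M21 position (mm10, counted from 1), and 99.1% of those positions overlapped the locus in the tables.

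Depth was read back from the FPKM values themselves. For 6228 genes with a single transcript of at least 1500 nucleotides, of which 1627 to 1780 gave values usable per library, a scale from FPKM to fragments was chosen so that most values became whole fragment counts within 0.1. This held for 61.0% to 66.3% of values, against 20.0% by chance. The resulting scale was 1.57 to 3.44 fragments per FPKM and kb of transcript, so 1 fragment on a transcript of 2 kb stood for 0.161 to 0.353 FPKM, and 5 FPKM for 14.2 to 31.0 fragments. These depths are estimates, the deposited tables hold no counts, and any precision drawn from them covers counting error only.

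Levels were compared as log2(FPKM + 1). The added 1 shrinks differences of low genes, and a difference against a library in which a gene is listed at 0 depends on it and is not a fold change. Genes with a mean of at least 1 FPKM over the libraries compared were kept (for comparisons across tissues, in either tissue). Tests used limma 3.58.1 with its mean trend in R 4.3.3, two-sided, with Benjamini-Hochberg adjusted p under 0.05. The strain difference (MSM minus B6) was fitted in each tissue on its 4 libraries with treatment as a block, which keeps each strain difference within 1 table and leaves 1 residual degree of freedom. Liver minus thymus was fitted on all 8 libraries with mouse as a block. A further fit on the liver minus thymus ratio of each mouse tested whether the change between untreated and injected mice, or the strain difference, differed between the tissues. In the strain and ratio fits, the spread measured is how far a difference varied between treatments or strains, moderated across genes. It is not the spread among mice of the same strain and treatment, since no combination was replicated. The injection itself was not tested within a tissue, since treatment coincides with the separately normalized table. For it, libraries were centred within each tissue by the median ratio over expressed genes, and genes were counted that were at least 2-fold higher or lower in the same direction in both strains, or whose change differed between the strains by at least 2 log2 units.

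These tests, the filters, 40 gene lists, the rule for named genes and most alternative settings were fixed before the data were examined. The rule took genes with a mean of at least 5 FPKM, leaving out, by symbol, predicted, unnamed and pseudogene names and those starting with Snor, Scarna or Mir: the 8 largest differences each way past the threshold with the same sign in both treatments for the strain tests, the 8 largest each way by the smaller of both strains' changes for the injection, and the 5 largest each way elsewhere (by size and unadjusted p where none passed). Members of the Fas apoptosis list, and the 4 members of each list with the largest difference, could also be named. Genes named outside this rule are marked as chosen after their values were seen. Some genes that the rule takes are not reported here. The lists hold 588 members, of which 584 were matched to the tables. A list's median was placed among 10000 random lists of the same size, drawn with replacement within 10 bins of mean expression (seed 1), as a description of these libraries. Of 346 list comparisons, 161 lay outside the central 95% of random lists.

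Alternatives were added values of 0.1 and 5 in place of 1, no filter and a filter of 5 FPKM, centring by the median ratio, rescaling to a common sum (TPM), limma without trend or with robust moderation, other model terms, and leaving out each library or mouse. A further alternative required status OK in every library, which every value carried, so it could change no result. After the data were seen, 2 alternatives were added, which left out small RNA genes or subtracted liver RNA from the MSM untreated thymus library. The code was tested on simulated data with negative binomial counts (dispersion 0.02, transcripts of 2 kb, 200 changed genes of at least 5 FPKM). At 4-fold the strain tests recovered 97.5% (liver) and 100% (thymus) of changed genes, the tissue test 100%, and the ratio tests 86% (injection) and 82% (strain). At 2-fold these shares were 43.5%, 60.5%, 93%, 10.5% and 16%. The counts in both strains recovered 98.5% (liver) and 99.5% (thymus) at 4-fold and 19.5% and 18% at 2-fold, and no changed gene was called in the wrong direction. Between 1 and 16 unchanged genes were called per simulation. The dispersion was set and not estimated from these libraries, and unchanged genes had equal means within a tissue. The shares recovered therefore do not give the power in the real data, where Lpin1 at 4.69 did not pass in the injection ratio. Of 100 unchanged simulated lists of 20 genes, 1 lay above and 2 below the central 95%, and all 100 lay above it when raised by 1 log2 unit. Data were read with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.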

Results

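Gene levels were measured by RNA sequencing in liver and thymus of 4 mice aged 8 weeks. The mice were C57BL/6 (B6), a classical laboratory strain, and MSM/Ms (MSM), a wild-derived Japanese strain. In each strain 1 mouse was untreated and 1 had received 1.5 µg of MegaFasL, a multimeric Fas ligand that engages the death receptor Fas, into the peritoneum. The time between injection and tissue collection was not given in the sources used here. Each combination of strain, tissue and treatment was 1 library, so no value of a single group has a replicate check. By the estimated depth, 1 FPKM on 1 kb of transcript stood for 3.44, 2.82, 3.36 and 3.10 fragments in thymus and 1.64, 1.73, 1.79 and 1.57 in liver, in the order B6 untreated, MSM untreated, B6 injected and MSM injected. Between 10412 and 11833 genes reached 1 FPKM in a library, and between 8319 and 10574 were listed at 0. Lars2 took 1.46% to 6.4% of the FPKM sum and Rn45s, a ribosomal RNA precursor named here after its values were seen, 2.3% to 9.02%.

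MSM and B6 livers differed in genes such as Cyp4a12b and Cyp2b9. MSM livers expressed the male-biased fatty acid hydroxylase gene Cyp4a12b at 154 FPKM untreated and 143 injected, and it was listed at 0 in both B6 livers (limma adjusted p = 0.00289). Akr1c18, which encodes a 20-alpha-hydroxysteroid dehydrogenase, was higher in MSM by 6.72 ± 0.31 (log2, SE, n = 2 mice per strain, 1 untreated and 1 injected, the design of every strain value here). This SE reflects how far the strain difference varied between untreated and injected mice, moderated across genes. Cyp2c39, a cytochrome P450, was higher by 5.53 ± 0.25. In the other direction the female-biased P450 gene Cyp2b9 (chr7:26173411-26210661, mm10, plus strand) was lower in MSM by 8.25 ± 0.26, with 435 and 359 FPKM in B6 livers and 0.690 FPKM and a listing at 0 in MSM livers. The MHC class I gene H2-K1 (chr17:33996017-34000347, minus strand) was lower in MSM by 8.24 ± 0.38.

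Higher in MSM liver were also Mup1 (a major urinary protein, 5.96 ± 0.38), Susd4 (a complement regulator, 47.3 and 57.3 FPKM), Ugt2b38 (a glucuronosyltransferase, 43.1 and 51.2 FPKM) and C1rb (a complement protease gene, 32.1 and 30.4 FPKM), and the last 3 were listed at 0 in both B6 livers. Rprl3, a small RNA gene related to ribonuclease P RNA, stood at 238 and 312 FPKM in MSM livers and was listed at 0 in B6. Lower in MSM were Sult2a2 (a steroid sulfotransferase, -7.02 ± 0.71), Mup3 (-6.90 ± 0.18), A1bg (a plasma glycoprotein, -6.80 ± 0.26), Cyp4a14 (-6.77 ± 0.27) and Kng2 (a kininogen gene, -6.53 ± 0.29). The ribosomal protein gene Rpl26 also passed, with 0 and 0.00535 FPKM in MSM livers, but it stood at 60.7 and 21.9 FPKM in MSM thymi, and such near-0 values are uncertain as levels. Of 10971 genes tested with limma, 56 were higher and 105 lower in MSM liver, 161 in all, and 1774 had an unadjusted p under 0.05. Values of Mup, Cyp2, Cyp4, H2, C1r and Kng family members are uncertain, since related genes share reads. Low MSM values in either tissue can also reflect lost reads of genes that diverge from the C57BL/6 reference. H2-K1, at 3.20 and 0.44 FPKM in MSM livers, may be such a case, which was not tested. Leaving out any 1 of the 4 liver libraries left 0 genes past the limma threshold, with 1494 to 1531 at an unadjusted p under 0.05.

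Sex-biased liver genes differed as groups. All 7 measured male-biased genes were higher in MSM, 3 past the threshold over all genes and 7 adjusted over the list alone, among them Cyp4a12a (4.39, limma adjusted p = 0.0147) and Cyp2d9 (4.28, adjusted p = 0.0147). Of 11 female-biased genes 5 were lower over all genes and 7 adjusted over the list alone, among them Cyp2b13 (-5.22), Sult2a1 (-4.81) and the steroid hydroxylase gene Cyp17a1 (-4.18). The list of Xist and Y-linked genes stood at a mean log2 level of 1.24 to 1.44 in every library. Only Xist of it was found (values under other observations, chosen after they were seen), which argues against mice of different sex as the source. Interferon-response genes had a median of -1.78 in MSM over 25 members. Of these, 3 were lower over all genes and 20 adjusted over the list alone, including Ifit3 (-3.72, adjusted p = 0.0371) and Usp18 (-3.00, adjusted p = 0.0463). Macrophage and Kupffer cell markers had a median of -1.65 over 14 members, with 2 lower over all genes and 11 adjusted over the list alone, such as lysozyme Lyz2 (-2.88) and the growth factor receptor gene Csf1r (-2.38). Genes of antigen presentation had a median of -1.06 over 13 members, with 2 lower over all genes and 8 adjusted over the list alone. The list holds H2 genes, whose MSM reads may be lost. Of 25 acute-phase genes, 2 were lower over all genes and 2 adjusted over the list alone, the plasma protein gene Orm1 (-2.44) and the hepcidin gene Hamp (-2.64). Among 15 immediate-early genes, the transcription factor gene Egr1 was higher (2.64, adjusted p = 0.0442), 1 member over all genes and 3 adjusted over the list alone. Thymocyte genes had a median of -0.79 over 11 members, and the B6 untreated liver held thymus-specific genes at 2.21% of the B6 thymus level, against 0.395% to 0.602% in the other livers. These 8 genes were chosen at 200 FPKM or more in every thymus and at most 5 FPKM in the other livers. The contrast between livers is therefore partly set by the choice.

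Fas, the receptor that MegaFasL binds (chr19:34290666-34327772, plus strand), stood at 31.2 FPKM in the B6 and 7.20 in the MSM untreated liver, and at 12.6 and 2.97 in the injected livers. The strain difference of -1.87 ± 0.27 did not pass over all genes (limma adjusted p = 0.0584). Under 4 of 15 alternatives it passed, and the adjusted p ranged from 0.0203 to 0.555. The 15, like the 16 used for thymus below, include requiring status OK in every library, which left the fit unchanged. The initiator caspase gene Casp8 stood at 13.8 and 6.31 FPKM untreated and 12.6 and 2.67 injected, a difference of -1.45 ± 0.34 (adjusted p = 0.156). The death-signal relay gene Bid differed by -1.28 ± 0.32 (adjusted p = 0.174), and the caspase-8 inhibitor gene Cflar by -0.40. Of 27 measured Fas apoptosis genes, 0 passed over all genes and 1 (Fas) was lower adjusted over the list alone, and the list median was -0.15. In thymus Fas stood at 27.9 FPKM in B6 and 8.83 in MSM untreated, and 17.3 and 15.0 injected, a difference of -0.88 ± 0.35 (adjusted p = 0.379) that passed under 0 of 16 alternatives, where the adjusted p ranged from 0.179 to 0.847. Of 29 Fas apoptosis genes measured in thymus, 0 passed over all genes and 0 adjusted over the list alone, with 1505 of 11610 thymus genes at an unadjusted p under 0.05 by limma. The gene of the ligand, Fasl, was at most 0.659 FPKM in every library.

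**Figure D1:**
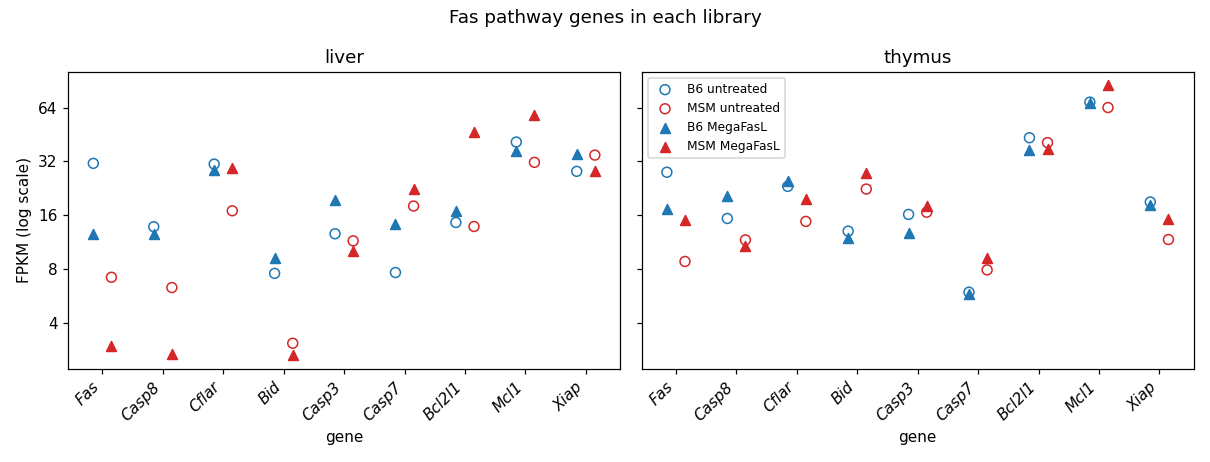
FPKM on a log axis of 9 Fas pathway genes in liver and thymus, 1 point per library, blue for B6 and red for MSM, open for untreated and filled for injected mice. Fas in liver stood at 31.2 and 12.6 FPKM in B6 and at 7.20 and 2.97 in MSM.

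In thymus, interferon-induced Ifi27l2a was at 53.4 and 50.1 FPKM in B6 thymi and listed at 0 in both MSM thymi (limma adjusted p = 0.000375). The MHC class II gene H2-Eb1 was lower in MSM by 5.56 ± 0.34, where lost reads of divergent MSM genes may contribute and were not tested. The membrane genes Ifitm2 and Ifitm1, which restrict virus entry, were higher in MSM by 4.72 and 3.52. The cell cycle regulator gene Spdya was at 28.0 and 35.7 FPKM in MSM thymi and listed at 0 in B6. Of 11610 genes tested with limma, 44 were higher and 69 lower in MSM, 113 in all, with 1505 at an unadjusted p under 0.05.

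Replication-dependent histone genes made up 6 of the 16 thymus genes named by rule. Hist1h2ak (-8.47 ± 0.43), Hist1h2bj (-7.91 ± 0.23), Hist1h4m (-7.67), Hist1h2bn (-7.24 ± 0.24) and Hist1h2bm (-4.81 ± 0.53) were lower in MSM, and Hist1h4i was higher (3.59). Nearly identical histone genes share reads, so single members are uncertain. The nonclassical MHC genes H2-T3 (4.33) and H2-Bl (3.47) were higher and Erdr1 was lower (-5.42). Rprl3 was higher in thymus too (7.80 ± 0.33). Interferon-response genes had a median of -1.0 over 27 members, with 2 lower over all genes, and 11 lower and 2 higher adjusted over the list alone, such as Oasl2 (-1.97, adjusted p = 0.0447). Of 15 antigen presentation genes, 3 were lower over all genes and 5 adjusted over the list alone, the class II genes H2-Aa (-1.77) and H2-Ab1 (-1.65) among them. Of 10 glucocorticoid-responsive genes, 1 was higher over all genes and 5 adjusted over the list alone, led by the kinase gene Sgk1 (3.15, adjusted p = 0.00786), at 37.7 FPKM in the untreated and 67.8 in the injected MSM thymus. Its members Pdk4 (31.9 and 3.45 FPKM) and Tat (12.4 and 1.33 FPKM) were instead higher in the untreated one, the library in which hepatocyte and fat markers stood high.

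Liver genes were also higher in MSM thymus, where 1 library stood apart. Of 19 hepatocyte markers, 1 was higher over all genes and 13 adjusted over the list alone, and Apoc3, a plasma lipoprotein gene, was higher by 4.32 ± 0.60 (adjusted p = 0.0389). In the MSM untreated thymus Alb, the serum albumin gene, stood at 1773 FPKM, against 24.1 in B6 untreated, 49.8 in B6 injected and 139 in MSM injected thymus. That library also held the airway secretory genes Scgb1a1 (400 FPKM), Scgb3a1 (316 FPKM) and Bpifa1 (415 FPKM), which reached at most 4.18 FPKM in the other thymi, and the brown fat gene Ucp1 (220 FPKM, against 7.81 to 13.7, chosen after its values were seen). Adipose and muscle markers had a median strain difference of 1.63 over 10 members, with 1 higher over all genes and 2 adjusted over the list alone. Without the MSM untreated thymus library 0 genes passed the limma threshold (1104 at an unadjusted p under 0.05), without the B6 untreated one 0 (1118), without the B6 injected one 51 and without the MSM injected one 36, of which 26 were higher and 10 lower in MSM. With the estimated liver RNA subtracted from that library, 391 genes passed, including all 113.

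**Figure D2:**
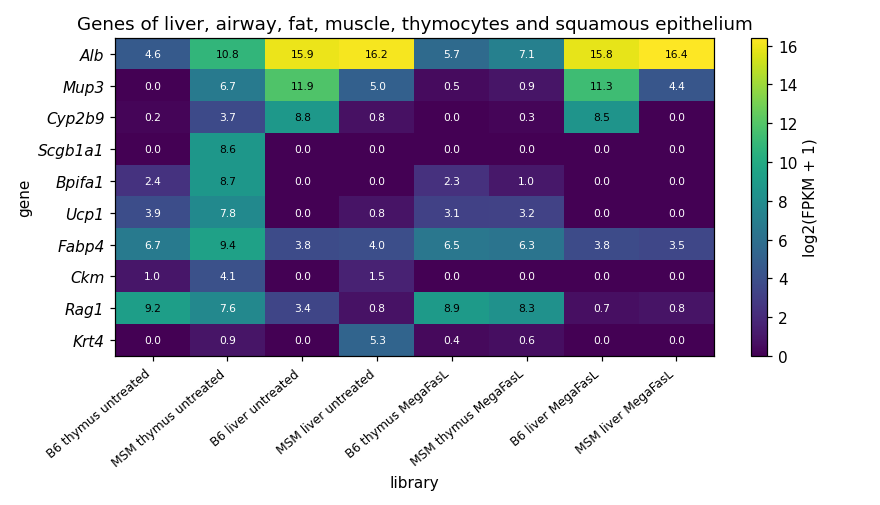
Heat map of log2(FPKM + 1) for 10 genes of liver, airway, fat, muscle, thymocytes and squamous epithelium in the 8 libraries. Scgb1a1 reached 400 FPKM in the MSM untreated thymus and was listed at 0 in the other 7 libraries.

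Liver and thymus of the same mice were parted by hepatocyte secretory genes and by thymocyte genes. The plasma protein genes Apoa2, Serpina3k, Ttr and Alb were higher in liver by 9.17, 9.07, 9.01 and 9.01 log2 units, and the fatty acid binding protein gene Fabp1 by 9.05 (Alb limma adjusted p = 0.000437). Rag1, which cuts antigen receptor genes during T cell development, was lower in liver by 7.08 ± 0.40 (n = 4 mice). The histone genes Hist1h2bl (-7.97), Hist1h3g (-7.49), Hist1h1b (-7.27) and Hist1h4a (-7.25) were lower in liver as well. Of 12880 genes, limma placed 3687 higher in liver and 4134 higher in thymus, 7821 in all, in the fit with mouse as a block. The split rests on the scaling: 47.1% of these were higher in liver as deposited, and 21.1% (2084 of 9872) after rescaling to a common sum, which moved the median over all genes from -0.13 to -1.05.

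After MegaFasL, clock genes differed from untreated liver alike in both strains. The clock output gene Dbp stood at 33.9 and 31.0 FPKM in injected B6 and MSM liver, against 1.65 and 1.96 untreated, differences of 3.66 and 3.41. The period gene Per1 differed by 3.43 and 3.24, and the clock-controlled protease gene Usp2 by 3.75 and 4.48. Arntl, which encodes the activating clock factor BMAL1, was at 1.15 and 0.527 FPKM injected against 9.22 and 17.5 untreated. Lpin1 (chr12:16535669-16610966, minus strand), which encodes a phosphatidate phosphatase, differed by 4.19 and 4.54. Treated and untreated levels come from separately normalized tables, and these differences were not tested.

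Of 10944 genes in liver, 180 were at least 2-fold higher and 136 at least 2-fold lower in both strains, 316 in all, against 95.5 if the strains' changes were independent, and 116 differed by 2-fold in opposite directions. The independent figure covers the same direction only. Across genes, which are not independent replicates, the strains' changes had a Pearson correlation of 0.18 and a Spearman correlation of 0.21. Named genes on the higher side also included Ppp1r3g, which directs a phosphatase to glycogen (3.19 and 3.81), the noncoding Snhg9 (listed at 0 in both untreated livers, 25.8 and 29.5 FPKM injected), the deadenylase gene Ccrn4l (4.03 and 2.96) and Hbb-b2, a beta globin with shared reads (3.61 and 2.89). On the lower side were the tubulin gene Tubb2a (-3.52 and -3.86), Clpx, a mitochondrial protease subunit (-2.59 and -2.46), Ddc, an aromatic amino acid decarboxylase (-2.22 and -2.27), choline kinase Chka (-1.85 and -2.12), the peptide gene Leap2 (-1.83 and -1.99) and histone Hist2h4 (-2.37 and -2.31).

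By list, 11 of 17 clock genes were at least 2-fold higher and 4 lower in both strains, with medians of 1.66 in B6 and 1.86 in MSM. Higher in both were also the clock repressor gene Nr1d1 (26.6 and 25.2 FPKM, against 7.78 and 5.72) and the output gene Tef (74.1 and 72.8 FPKM, against 7.86 and 11.7). Lower in both beside Arntl were Clock (-1.36 and -1.43), Cry1 (-1.45 and -1.06, chosen after its values were seen) and Nfil3 (-1.98 and -1.76). Glucocorticoid-responsive genes had medians of 1.08 and 1.75 over 10 members, with 4 higher in both strains, among them the chaperone gene Fkbp5 (2.02 and 3.87) and Zbtb16 (2.37 and 2.13). Of 14 heat shock genes 4 were higher in both, such as Hspa1b (1.68 and 3.05) and Dnajb1 (1.65 and 1.30). The metallothionein genes Mt1 (2.15 and 5.14) and Mt2 (2.61 and 4.33) and the iron-binding acute-phase gene Lcn2 (1.54 and 3.11) were 3 of 25 acute-phase genes at least 2-fold higher in both. Within the Fas apoptosis list, 2 of 27 members were at least 2-fold lower in both strains, Fas (-1.31 and -1.07) and Endog, a mitochondrial nuclease gene (-1.36 and -1.06), and 0 higher.

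**Figure D3:**
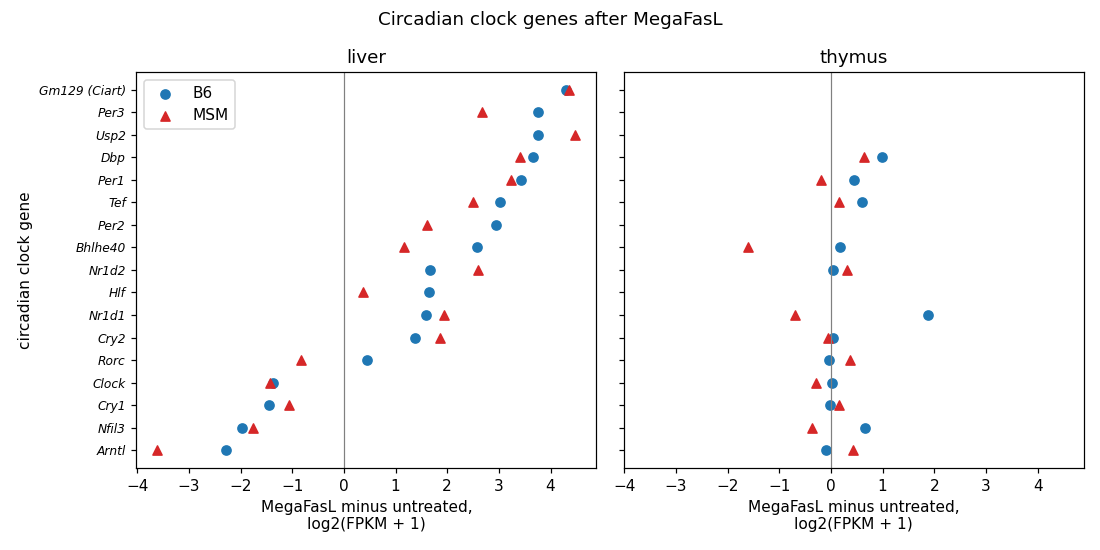
Difference in log2(FPKM + 1), injected minus untreated, for clock genes in liver and thymus, blue circles for B6 and red triangles for MSM, 1 pair of libraries each. In liver 11 of 17 genes were at least 2-fold higher and 4 lower in both strains.

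Other liver groups went with 1 strain, and none of these differences was tested. Immediate-early genes, which answer stimuli within minutes, had medians of 0.04 in B6 and 1.47 in MSM. Of 15 members, 8 were 2-fold higher in MSM alone, such as Fos (-0.36 and 3.44) and Junb (0.19 and 1.72), and 2 in both, Egr1 (1.84 and 2.51) and Maff (2.33 and 2.73). NF-kappaB target genes had medians of -0.15 and 0.84 over 17 members. The chemokine genes Cxcl1 (36.6 FPKM injected, 3.87 untreated) and Ccl2 (10.5 FPKM, listed at 0 untreated) and Tnfaip3, which limits NF-kappaB signalling (8.01 FPKM, listed at 0 untreated), were among 6 higher in MSM alone. The acute-phase gene Saa1 differed by -0.92 and 3.48. Bcl2l1, which encodes the survival protein BCL-XL, stood at 46.9 FPKM in the MSM injected liver against 13.9 untreated, and at 16.9 against 14.6 in B6. Casp6 (-0.84 and 1.14) and Birc3 (-0.09 and -1.44) also differed between the strains.

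Lipid and blood cell genes parted the strains as well. Of 20 cholesterol synthesis genes, 12 were 2-fold higher in B6 alone, with medians of 1.12 and -0.33. Idi1 (1.48 and -1.12) and Mvk (1.23 and -1.47) went opposite ways. Of 13 lipogenesis genes, 5 were 2-fold lower in MSM alone, such as fatty acid synthase Fasn (1.71 and -1.42) and the regulator Srebf1 (0.23 and -1.57). Erythroid genes had medians of -0.09 and 2.89 over 7 members, led by Hba-a2 (-0.09 and 8.27), a globin with shared reads, and the heme synthesis gene Alas2 (-0.07 and 3.49). Macrophage markers had medians of -1.08 and -0.08, with 9 of 14 2-fold lower in B6 alone. Thymocyte genes had medians of -1.48 and 0.04, with 6 of 11 lower in B6 alone, and it is the B6 untreated liver in which the chosen thymus-specific genes stood at 2.21%. With a filter of 5 FPKM the B6 thymocyte median was 0.36. In all 233 genes differed by at least 2 log2 units towards MSM and 220 towards B6, 453 together. The named ones were Hba-a2, Rpl34 (-1.06 and 6.81), Hist1h4a (-3.57 and 4.14), Hist1h4k (-4.12 and 2.71) and Hist1h2bb (-3.00 and 2.51), families with shared reads. In that B6 untreated liver Hist1h4a stood at 10.8 and Hist1h2bb at 22.9 FPKM, against 517 and 880 in the B6 untreated thymus. On the other side were Cyp3a16 (2.64 and -3.31), the bile acid transporter gene Slc10a2 (1.65 and -2.90), the small nuclear RNA Rnu11 (183 FPKM in the MSM untreated liver) and the squamous keratins Krt4 (37.1 FPKM) and Krt13 (31.2 FPKM), the last 3 listed at 0 in the other livers. Rnu11 is short, so few fragments can give it a high FPKM.

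**Figure D4:**
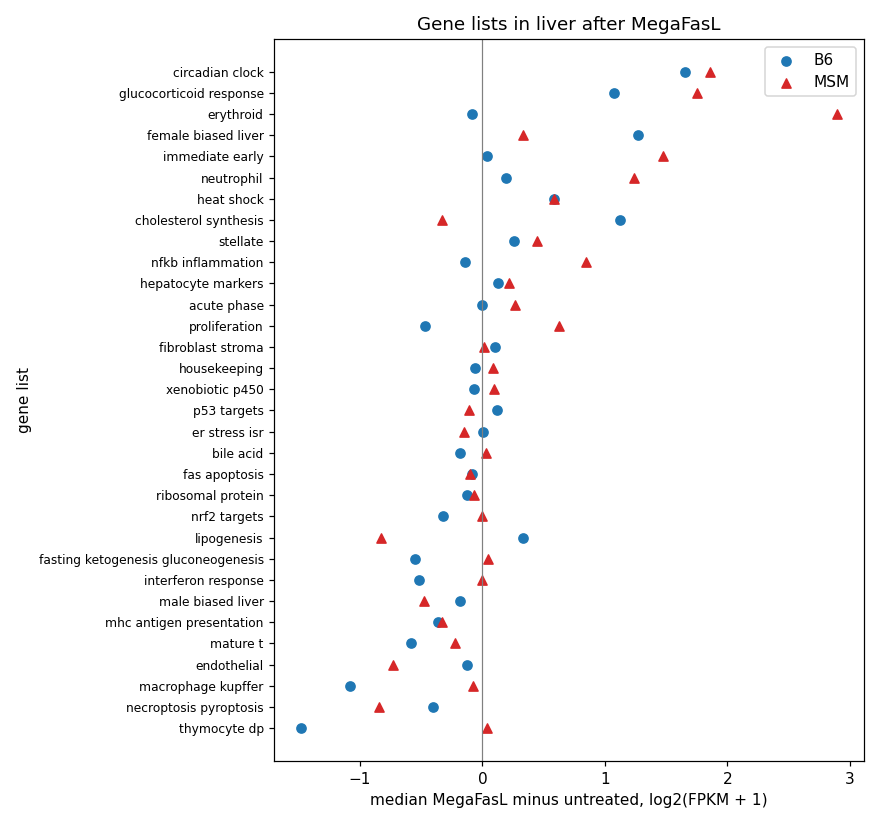
Median difference in log2(FPKM + 1), injected minus untreated liver, of each gene list, blue circles for B6 and red triangles for MSM. Clock genes stood at 1.66 and 1.86, immediate-early genes at 0.04 and 1.47.

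In thymus, fewer genes than in liver differed alike in both strains after MegaFasL. The glucocorticoid-induced leucine zipper gene Tsc22d3 differed by 1.34 in B6 and 1.69 in MSM, Fkbp5 by 1.25 and 1.42, and the chaperone gene Hsph1 by 1.30 and 1.67. The neutrophil and myeloid calcium-binding gene S100a9 differed by 3.00 and 4.71. Erythrocyte genes were lower, with Hba-a1 at -2.17 and -3.14 and Beta-s at -1.61 and -3.73. Of 11615 genes 31 were 2-fold higher and 49 lower in both strains, 80 in all, against 23.6 if independent, and 67 went opposite ways, with a Pearson correlation of 0.03 across genes. The independent figure covers the same direction only. Genes that vary in both strains raise the counts in both directions, so the 80 do not by themselves show a shared change. With 5 added in place of 1, 16 were higher and 9 lower. Each MSM change here is set against the MSM untreated thymus, the library with RNA of other tissues. In MSM 228 genes were at least 2-fold higher and 1079 lower, against 243 and 203 in B6. None of this was tested.

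Further thymus genes higher in both were the aldose reductase gene Akr1b3 (8.75 and 19.0 FPKM, against at most 0.00334 in the other 6 libraries, values uncertain as levels), the ubiquitin ligase gene Rnf5 (1.48 and 1.81), H2-Q8 (1.43 and 1.54, shared reads) and Meaf6, a histone acetyltransferase subunit (1.15 and 1.27). Lower in both were S100a6 (-1.87 and -1.99), the ubiquinone synthesis gene Coq7 (-1.88 and -1.78), the muscle light chain Mylpf (-1.44 and -1.82), Lars2 (-1.43 and -1.69), the cysteine dioxygenase gene Cdo1 (-1.37 and -3.21) and the biliverdin reductase gene Blvrb (-1.34 and -1.33). The MSM untreated thymus held Mylpf at 21.8 and Cdo1 at 94.7 FPKM, against 7.35 and 12.2 in the B6 untreated thymus, so their MSM changes may reflect its RNA of other tissues. Lars2 took 3.72% and 6.4% of the FPKM sum in untreated B6 and MSM thymus and 1.46% and 1.88% injected. Whether its reads come from the gene itself was not tested, so it is uncertain as a level. Of 10 glucocorticoid-responsive genes 2 were higher in both, of 14 heat shock genes 2, of 6 neutrophil markers 2, and of 5 erythroid genes 3 were lower in both. Double-positive thymocyte genes had medians of 0.07 and 0.44, where the MSM untreated thymus, the library with RNA of other tissues, had the lowest mean log2 level of the list (6.15, against 6.61 to 6.85 in the other thymi). In the Fas apoptosis list, 1 of 29 members was 2-fold lower in both strains, the survival gene Bcl2a1d (-1.01 and -1.79), and Fas itself differed by -0.70 and 0.63. Bcl2a1d stood at 3.91 and 4.18 FPKM in untreated B6 and MSM thymus and at 1.50 and 0.540 injected, low levels at which a change is imprecise. The related Bcl2a1b, which may share reads with it, differed by -0.31 and 0.50.

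Thymus changes that differed between the strains ran mostly towards lower values in MSM, 433 genes against 78 (511 together). All 19 measured hepatocyte markers were 2-fold lower in MSM alone (median -3.48, against 0.57 in B6), as were 9 of 10 adipose and muscle markers (-2.93 against -0.13) and 10 of 11 B cell markers (-1.98 against -0.18). In each case the MSM value is set against the untreated MSM thymus library with 1773 FPKM of Alb. Among the named genes, Scgb3a1 differed by 2.01 and -8.34, Bpifa1 by -0.10 and -7.71, and the lymph node vessel gene Glycam1 by 0.76 and -6.14, and Scgb1a1 was listed at 0 in the other thymi. A larger value in MSM than in B6 was also given by Rnu11 (-8.55 and 6.64), the adaptor gene Hcst (-1.22 and 3.14), S100a8 (-0.44 and 3.44) and Hist1h2ah (-1.86 and 1.38). The respiratory chain gene Ndufs5 entered with -5.25 in B6, from 36.9 to 0.0149 FPKM, and at most 0.00364 FPKM in the MSM thymi, where such near-0 values are uncertain as levels. Rnu73b was at 489 FPKM in the B6 injected thymus and listed at 0 in the other libraries. Rnu73b and Rnu11 are shorter than the fragment length of 200 nucleotides used for the depth estimate. Few fragments can give them a high FPKM, so their values are uncertain as levels. With liver RNA subtracted, the count was 319, of which 83 were higher and 236 lower (26.0% higher against 15.3%).

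A test of whether the injected minus untreated difference itself differed between liver and thymus was possible through the ratio within each mouse. Among genes that the rule for named genes admits, with an unadjusted p under 0.05, the largest differences towards liver were those of Thrsp, a lipogenic nuclear protein gene (4.77, limma adjusted p = 0.247), Lpin1 (4.69 ± 0.49, n = 2 mice per treatment, adjusted p = 0.238), Usp2 (4.19), the signalling regulator gene Rgs16 (4.18) and the beta globin Beta-s (4.10 ± 1.28). The Beta-s value came mostly from the MSM mice (3.26 in liver and -3.73 in thymus, against -0.38 and -1.61 in B6), among them the mouse whose untreated thymus library stood apart. That thymus library held Thrsp at 93.2 FPKM. In B6 and MSM, Thrsp differed by 2.34 and 1.98 in liver and by -1.28 and -3.96 in thymus. Towards thymus they were those of Akr1b3 (-3.80), the leukotriene synthesis gene Alox5ap (-3.40), Arntl (-3.15), S100a9 (-3.13) and Hist1h3a (-2.96). None of these 10 passed. Only 5 of 12880 genes did, all small RNA genes and named here after their values were seen: Snora30 (7.32) and Snora44 (6.13) towards liver and Snord49b (-12.02), Snora5c (-8.30) and Snora33 (-8.55) towards thymus, with 974 genes at an unadjusted p under 0.05. Leaving small RNA genes out left 0 (1066 at an unadjusted p under 0.05). Such short genes can rest on few fragments in polyadenylated RNA, so these 5 values are uncertain as levels.

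For the clock list the ratio test had 0 of 18 members past over all genes and, adjusted over the list alone, 11 higher and 4 lower in liver relative to thymus, with a median of 1.78. Adjusted over the list alone, 7 of 25 acute-phase, 5 of 13 lipogenesis, 5 of 11 female-biased, 4 of 10 glucocorticoid-responsive and 4 of 7 erythroid genes were higher, all with 0 past over all genes. The acute-phase, lipogenesis and female-biased members are liver genes, as is Tat in the glucocorticoid list, and the MSM untreated thymus held liver RNA. A small share of liver RNA does not give its 93.2 FPKM of the lipogenesis gene Thrsp, which stood at 87.4 FPKM in the B6 untreated liver. Adipose and muscle markers had a median of 1.51 in this comparison, with 7 of 10 at least 2-fold higher. In this comparison the hepatocyte markers had a median of 1.66 over 22 members and the xenobiotic P450 genes 1.30 over 14, beside 1.51 for the glucocorticoid list. The ratio alone thus does not set that list apart from liver genes. Within liver (B6 and MSM) its medians were 1.08 and 1.75, against 0.13 and 0.21 for hepatocyte markers. Within thymus they were 0.35 and -0.09, against 0.57 and -3.48. The erythroid list holds Beta-s. For Fas the difference was -1.17 (adjusted p = 0.646).

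The same ratio tested whether the strain difference differed between tissues. The difference (MSM minus B6) in liver minus that in thymus was positive for Cyp4a12b (6.93, limma adjusted p = 0.0108), Akr1c18 (6.71), Ugt2b38 (5.58), Susd4 (5.12) and Hist1h2ak (6.30, from -8.47 in thymus and -2.17 in liver), and negative for Cyp2b9 (-10.12, adjusted p = 0.0136), Cyp4a14 (-8.48), A1bg (-8.36), Kng2 (-8.07) and Sult2a2 (-8.07), the last 5 being genes with lower levels in MSM than in B6 liver. Of 12880 genes, 14 were higher and 33 lower, 47 in all, with 1626 at an unadjusted p under 0.05. These Cyp2b9, Cyp4a14, A1bg, Kng2 and Sult2a2 values include their traces in the MSM untreated thymus, 3.29 to 12.4 FPKM. Hist1h2ak, a histone gene with shared reads, stood at 19.2 FPKM in the B6 untreated liver and was listed at 0 in the other livers. It stood at 666 FPKM in the B6 untreated thymus, and that B6 liver held the chosen thymus-specific genes at 2.21%. Of the 47, 29.8% were higher as deposited, against 41.2% of 17 with centred libraries and 62.5% of 8 after rescaling to a common sum. Female-biased liver genes had 4 lower over all genes and 7 adjusted over the list alone, and macrophage markers 0 and 10, of 15 measured.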

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

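All tests of explanations in this part, and the splits of the libraries, were chosen after the results were seen, while the ratio tests by limma were planned. Mean levels of the 16 cell type marker lists were compared among the 4 libraries of each tissue, 32 comparisons in all, and 2 had a library far from the other 3. Endothelial markers stood at a mean log2 level of 2.76 in the MSM injected liver, with a gap of 0.851 of the whole range. Adipose and muscle markers stood at 5.36 in the MSM untreated thymus, with a gap of 0.93 of the range. Chance gives such a gap in about 1 in 20 groups.

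Strain differences that differed between liver and thymus in the limma test numbered 47, and changes with injection that differed between the tissues numbered 5. Among the named genes the strain difference (MSM minus B6) in liver minus that in thymus was positive for Cyp4a12b (6.93), Akr1c18 (6.71), Ugt2b38 (5.58) and Susd4 (5.12), and for Hist1h2ak (6.30), whose difference was -8.47 in thymus and -2.17 in liver. It was negative for Cyp2b9 (-10.12), Cyp4a14 (-8.48), A1bg (-8.36), Kng2 (-8.07) and Sult2a2 (-8.07). The liver part of Hist1h2ak, a histone gene with shared reads, rests on 19.2 FPKM in the B6 untreated liver, since it was listed at 0 in the other livers.

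The injected minus untreated difference went opposite ways in the strains for 116 liver genes at 2-fold, and this was not tested. In B6 and MSM liver the values were -1.06 and 6.81 for Rpl34, -3.57 and 4.14 for Hist1h4a, -4.12 and 2.71 for Hist1h4k, and -3.00 and 2.51 for Hist1h2bb. In the B6 untreated liver the chosen thymus-specific genes stood at 2.21%. They were 2.64 and -3.31 for Cyp3a16 and 1.65 and -2.90 for Slc10a2. In thymus 67 genes went opposite ways, also not tested. There the values were -8.55 and 6.64 for Rnu11 (a short gene, uncertain as a level), -1.22 and 3.14 for Hcst, -1.86 and 1.38 for Hist1h2ah, and 2.01 and -8.34 for Scgb3a1.

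The MSM untreated thymus library held transcripts of liver, fat, muscle and airway. For liver RNA of MSM origin, 5 genes specific to MSM liver stood at a median of 0% of their MSM liver level (upper quartile 0.054%), and a trait of the MSM thymus present with and without injection would leave the hepatocyte markers alike in both MSM thymi, yet 19 markers had a median of -3.48, injected minus untreated (quartiles -3.78 and -2.83), which argues against both, while a trait ended by injection stays open. Genes specific to B6 liver, 9 in all, stood at a median of 2.61% of the B6 untreated liver level (quartiles 2.14% and 2.77%), so RNA of a B6 liver may be present, by a route that the data do not show. That share would give at most 17.9% of any fat or muscle marker (Car3, which liver also expresses) and at most 0.0482% of the other 9, which argues against liver RNA as the main origin of these markers, under a bound of 50% per marker that replaced one of 10% after the values were seen, since the stricter bound was wrong for a gene that liver expresses at 1544 FPKM. Tissue next to the thymus and other origins of these markers cannot be told apart, because the 10 of 10 adipose and muscle markers at least 2-fold above every other thymus library are the observation itself and no independent test, and no test covered the airway genes.

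Clock genes differed between injected and untreated livers in both strains. Scaling between the separately normalized tables would move genes of opposite phase alike. The smallest gap between the medians of the 2 phase groups over the strains and scalings was 4.14 log2 units. The groups, with 16 genes measured in liver, were drawn up after the results were seen, so this gap is partly set by the grouping. In the clock list fixed beforehand, 11 of 17 genes were at least 2-fold higher and 4 lower in both strains. Changes in both directions argue against scaling. Another time of day at collection could give this pattern. In liver, 16 of 16 phase-group genes moved in the direction of their group in both strains, a count that is also partly set by the grouping. Glucocorticoid release with injection or handling could give the pattern too, where 3 of 9 glucocorticoid-responsive genes other than Per1 were at least 2-fold higher in both injected livers. In thymus the same gap was 0.441 in B6 and 0.0067 in MSM over 11 genes. These explanations and an effect of MegaFasL itself cannot be told apart, because treatment, handling and collection coincide in the design and 1 mouse stands for each combination.

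Immediate-early genes stood higher in the MSM injected liver. Scaling of that library is argued against by a gap of at least 1.47 log2 units between their median and that of all genes over the scalings. Leukocytes entering the liver might contribute, but 22 leukocyte markers had a median of 0.19 there, and because they span cell types whose own medians differ (1.24 for 3 neutrophil and -0.08 for 14 macrophage markers), this explanation and a response of liver cells cannot be told apart. A strain difference in the response to MegaFasL stays open and untested.

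For liver minus thymus, the real split of the 8 libraries gave 7821 genes past the limma threshold. It parts all 4 pairs of libraries from 1 mouse, as do 8 splits in all, of which 1 gave as many genes, the real one, and the highest other gave 0, and 8 splits are too few for a share under 0.05. The remaining splits part fewer pairs: 24 part 2 pairs, with at most 1 gene, and 3 of the 35 in all could not be fitted with mouse as a block.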

How the results depend on the processing

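The alternatives that left out small RNA genes or subtracted liver RNA were chosen after the data were seen. For values below, the cause was not tested unless stated, and main counts were 161 (strain, liver), 113 (strain, thymus), 7821 (tissue), 5 (injection ratio), 47 (strain ratio), 316 and 80 (both strains, liver and thymus) and 453 and 511 (strain difference in the injected minus untreated change, liver and thymus). The tissue count stayed between 6268 and 9872 under every alternative run, including 8130 without the mouse block. With 0.1 added in place of 1, counts were 300 (strain, thymus), 1, 5 (80% higher), 552, 231 (60 higher, 171 lower), 1091 and 1034, in the order above, and with 5 added they were 132 (strain ratio), 107, 25 (16 higher, 9 lower), 96 and 176. Without a filter, limma gave 0 for both strain tests and both ratios (1691, 1540, 1179 and 1681 genes at an unadjusted p under 0.05), with 23284 genes tested. With a filter of 5 FPKM, counts were 184 (strain, thymus), 3, 15, 197, 39, 192 and 219. With centred libraries they were 61 (strain, thymus), 3 and 17 (41.2% higher). After rescaling to TPM they were 336 (strain, liver), 45, 1 (0 higher, 1 lower), 8 (62.5% higher), 297 (both strains, thymus), 722 (strain difference, liver, 40.6% higher against 51.4%) and 1413. Rescaling moved the median of all genes by over 0.1 in strain liver (from 0.01 to -0.16), tissue (from -0.13 to -1.05), the MSM liver change (from 0.02 as deposited to -0.11) and the MSM thymus change (from 0.07 as deposited to -0.10). Without trend, limma gave 37, 44 and 26 for the strain tests in liver and thymus and the strain ratio, and robust moderation gave 274 (strain, thymus) and 30 (strain ratio). Fitted on all 8 libraries, strain in thymus gave 44.

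With liver RNA subtracted, counts were 391 (strain, thymus), 78 (strain ratio) and 319 (strain difference, thymus), and without small RNA genes 190 (strain, thymus), 0 (injection ratio, 1066 at an unadjusted p under 0.05) and 98 (strain ratio). Leaving out 1 library gave 0 to 0 in liver and 0 to 51 in thymus for the strain tests (26 higher and 10 lower without the MSM injected thymus), where the pair left is assumed to vary as the other tissue does. Requiring 1 strain alone gave 1386 to 1508 in liver and 446 to 1307 in thymus, as fewer conditions have to be met. Directions reversed for 5 list medians: thymocyte genes in B6 liver (0.36) and in the strain difference in liver (-0.15) with the filter of 5 FPKM, bile acid genes in MSM thymus (0.36) and in the strain difference in thymus (0.34) with liver RNA subtracted, and neutrophil genes in the strain difference in thymus after TPM (-0.0299). Of the other named genes and list medians under alternatives, 1676 values kept their side, 330 moved in size, 229 lost and 4 gained the threshold. Of the 1676, 236 came from requiring status OK in every library, which every value carried, so they could not differ from the main values. At these depths 5 FPKM rests on 14.2 to 31.0 fragments of a 2 kb transcript, so changes near that level are imprecise.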

Other observations

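No test was planned for the values in this part. Fasting and gluconeogenesis genes in injected livers, 16 measured and not tested, went several ways. The insulin-like growth factor binding protein gene Igfbp1 stood at 542 FPKM in the MSM injected liver against 34.2 untreated, and differed by -0.61 in B6. The coactivator gene Ppargc1a differed by 0.92 in B6 and 3.12 in MSM. Pck1, which encodes the gluconeogenic carboxykinase, was the 1 member at least 2-fold higher in both strains (1.58 and 1.45), and Cyp4a14 the 1 at least 2-fold lower in both (-1.19 and -1.84). Another 4 members were 2-fold higher in MSM alone and 4 lower in MSM alone, such as Cyp4a10 (-0.49 and -2.03). Proliferation genes had medians of -0.47 and 0.63 over 12 members in liver. The B6 value is set against the B6 untreated liver, the liver with the highest share of the chosen thymus-specific genes. There the mean log2 level of the list was 1.51, against 0.845 to 1.36 in the other livers and 5.06 in the B6 untreated thymus. Endothelial markers had medians of -0.13 and -0.73 over 11. Female-biased liver genes had medians of 1.27 in B6 and 0.33 in MSM, and interferon-response genes -0.52 and 0.00.

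Xist, which is transcribed from the inactive X chromosome, stood at 73.0 to 148 FPKM in all 8 libraries, and the Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y were listed at 0 in all 8, genes chosen after their values were seen. The B cell marker Ms4a1 stood at 13.8 FPKM in the MSM untreated thymus. In the tables, the upper confidence bound lay below the value itself for 6 to 11 genes per library. The 159 genes abundant in all 4 livers stood at a median of 3.26% of the same mouse's liver level in the MSM untreated thymus, against 0.0862% in B6 untreated, 0.120% in B6 injected and 0.211% in MSM injected thymus. They were chosen at no more than 20 FPKM in the thymi other than MSM untreated, so this contrast is partly set by the choice. Thymus-specific genes, chosen as low in the other livers, stood at 2.21% (quartiles 1.81% and 3.86%) in the B6 untreated liver. Rag1 was at 9.88 FPKM there, against 0.601 to 0.787 in the other livers.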
